A study of Mus musculus with 6 samples.

How the data were processed

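Chromatin accessibility was measured by ATAC-seq (assay for transposase-accessible chromatin with sequencing), in which the Tn5 transposase cuts and tags open DNA, in medullary thymic epithelial cells with high surface MHC class II. These cells, called mTECs below, present self-antigens to developing T cells in the thymus. The labels give 3 wildtype and 3 Kat7-knockout libraries on the C57BL/6 background, each from its own biological replicate per the design text, and paired-end reads of 75 bases. KAT7 is a histone acetyltransferase of the MYST family, which acetylates histone H3 at lysine 14 among other residues. Neither the driver of the deletion nor the deleted part of Kat7 is given in the sources used here.

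The deposited values were whole-number counts per gene window for each library, made by the authors with featureCounts on mouse build mm10, per the submitters' processing notes. The aligner, the handling of duplicate reads, any shift of reads for the transposase offset, and whether fragments or single ends were counted are not given in the sources used here. Duplicates and mitochondrial reads can raise single windows, and a missing shift moves cuts by a few bases, which is small beside windows of this size. Per the file headers and coordinates, each of 27095 genes had 1 window. The windows reached from 3000 bases upstream to 2000 bases downstream of a gene start, and 5115 of them were shorter. In an annotation of the same strain, which held 25204 of the gene identifiers, the gene start lay exactly 3000 bases into the window for 12793. Why the others differed was not tested. All 6 libraries' own tables held the same counts as the table of the whole series. The values therefore report promoter accessibility of each gene, not expression and not distal elements.

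Windows of neighbouring genes overlapped: 6243 windows shared at least 1 base with another window. The 482 windows lying wholly inside others had a median count of 0 per library, against 224.3 for the 20852 windows sharing no base, and the 4340 windows with most of their length inside others had a median of 18.17. Reads in shared stretches therefore appeared to be left out of the counts, and the counts of overlapping windows, such as that of Aire, report only the unshared part. Symbols came from the files. For 1280 windows without one, a symbol was looked up by gene identifier in an annotation table of assembly GRCm38.p6, which filled 16, and the table also gave older names for list genes and gene lengths. Of 596 list entries, 595 matched a window.

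Counts were tested in R 4.3.3 with edgeR 4.0.16. Windows with low counts were removed with filterByExpr at its default settings, which left 24817. Libraries were scaled with TMM factors, which lay between 0.884 and 1.057, and tested with the robust quasi-likelihood pipeline (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment at 0.05. The labels' replicate numbers were not used as a block. Every adjusted p given for a gene comes from this test unless another is named. The biological coefficient of variation was 10.9%. Levels are given as CPM, the counts scaled to library size and TMM factor, with the mean ± SD of 3 libraries, and log2 fold changes are knockout against wildtype with their standard error (SE). The values of single measures were compared by exact two-sided permutation of the 6 libraries, which cannot give a p below 0.1 with 3 against 3. A count of 3 served as the limit that 0 counts allow; this and the tests on reads cover counting error only, since reads without molecular identifiers are not independent molecules.

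Gene lists were tested as sets with camera in limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation preset to 0.01, two-sided, and Benjamini-Hochberg adjustment over 46 lists with at least 5 tested windows. Camera with the correlation estimated from the data was the strict alternative, and fry a test of each list by itself. For each list the number of windows past the threshold over all genes, the number adjusted over the list alone, the median and the percentile of that median among 10000 random lists matched on mean accessibility in 50 bins were computed. The 34 lists of named genes covered mTEC maturation and antigen presentation, CCL21-producing mTECs, epithelial identity, cortical thymic epithelium, genes known from the literature as AIRE-induced or FEZF2-dependent, tissue genes (liver, pancreas, secretory glands, intestine, neurons and retina, testis), mTEC subsets that resemble peripheral cells (keratinocytes, tuft cells, microfold cells, neuroendocrine cells, ciliated cells, muscle, ionocytes, enterocytes and hepatocytes), KAT7 complexes, other acetyltransferases, AIRE partners, NF-kB, interferon, cell cycle, p53 and housekeeping genes, and markers of other cells a sort can carry along (thymocytes, B cells, myeloid and dendritic cells, mesenchymal, endothelial and erythroid cells). The 12 families were taken by symbol: ribosomal protein, olfactory receptor, vomeronasal receptor, defensin, major urinary protein, Klk1b kallikrein, keratin-associated protein, Hox, histone, zinc finger (Zfp), clustered protocadherin, and Spink and Serpin genes.

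The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. The rule named Kat7 and Aire; the 10 largest log2 fold changes and the 5 smallest p in each direction among windows past the threshold with every knockout library on one side of every wildtype library, a mean count of at least 20 and a symbol that is not a predicted model; and up to 4 windows with the smallest p from each list that passed its test or held a window past the threshold, or up to 2 from any other list. Named outside this rule, and chosen after their values were seen, were Dlx3, Tac4, Fam117a, Slc35b1, Spop, Dlx4os, Unc119, Slc13a2, Pigs, Slc46a1, Aldoc, Proca1 and Rab34 as neighbours, the Tas2r family, and, as further members of lists, Fezf2, Cd80, H2-Aa, Ccl21a, Epcam, Foxj1, Pou2f3, Dclk1, Trpm5, Ins2, Wfdc18, Cdx2, Alb, Prss16, Tbata, Ctsl, Blnk, Bcl11b and Zbtb46. Alternatives covered scaling (DESeq2 size factors, library totals, TMM on the quartile of windows with the highest counts, loess by mean accessibility), tests (DESeq2 1.42.0, limma-voom with and without sample weights, a test against a 1.2-fold change), filters on low counts, a replicate block, and leaving out each library in turn. Windows sharing no base, and libraries 2 and 3 of each group alone, were added after the data were seen.

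The same code was tested on simulated counts for the comparison of knockout with wildtype over 24817 windows. It recovered 36.8% of 68 windows changed 1.5-fold, 65.2% of 66 changed 2-fold and 89.4% of 66 changed 4-fold, and 3 of its 130 calls (2.31%) were unchanged windows. A change of 1.5-fold was therefore often missed in this simulation, in which few windows changed. Far more windows passed in the real comparison, which loosens the adjusted threshold, so the share missed there is not known. Motif content, distal peaks and nucleosome positions were not analysed here, since no genome sequence, reads or peak calls were used.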

Results

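Promoter accessibility was counted in 6 ATAC-seq libraries of medullary thymic epithelial cells with high MHC class II, 3 from wildtype and 3 from Kat7-knockout mice. Library totals were 19832326, 15494911 and 16388648 counts in wildtype libraries 1 to 3 and 19740835, 16107353 and 15482439 in knockout libraries 1 to 3. They did not differ between groups (exact two-sided permutation p = 0.7, n = 3 per group, where the smallest p the design allows is 0.1). Between 26482 and 26560 of 27095 windows had a count above 0, and a count of 3, the limit that 0 counts allow, corresponded to 0.154 to 0.192 CPM. Log2 CPM correlated across windows at Pearson's r between 0.987 and 0.993 within groups and between 0.963 and 0.978 across groups; windows are not independent replicates. The comparison of knockout with wildtype asks which promoters gain or lose accessibility in these cells when the histone acetyltransferase KAT7 is missing.

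The promoter of Kat7 itself lost most of its signal. Its window (gene identifier 217127, chromosome 11, 95308246 to 95313246, mm10) held 267 ± 26.5 CPM in wildtype and 21.2 ± 14.9 CPM in knockout (SD, n = 3 each), a log2 fold change of -3.66 (SE 0.574, adjusted p = 0.0143). Raw counts were 5672, 3729 and 4606 in wildtype and 208, 221 and 627 in knockout libraries 1 to 3. The knockout libraries kept 4.46%, 4.94% and 14.4% of the wildtype mean. Since the deleted part of Kat7 is not known, removal of DNA from this window cannot be told apart from a loss of accessibility. Every knockout library lay below every wildtype library (exact permutation p = 0.1, the smallest possible). The adjusted p exceeded 0.05 without wildtype library 1 (0.0643), without wildtype library 3 (0.0565) and with libraries 2 and 3 of each group alone (0.0658), within a range over the alternatives of 0 (too small to be stored, limma-voom with sample weights) to 0.0658, and the log2 fold change was -4.41 without knockout library 3. Among neighbouring promoters, that of the homeobox gene Dlx3 (log2 fold change -0.65), that of the tachykinin gene Tac4 (-0.64) and the overlapping window of Dlx4os (-1.25) fell, while Fam117a (-0.23, adjusted p = 0.178), Slc35b1 (0.13) and Spop (0.15) did not pass.

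**Figure D1:**
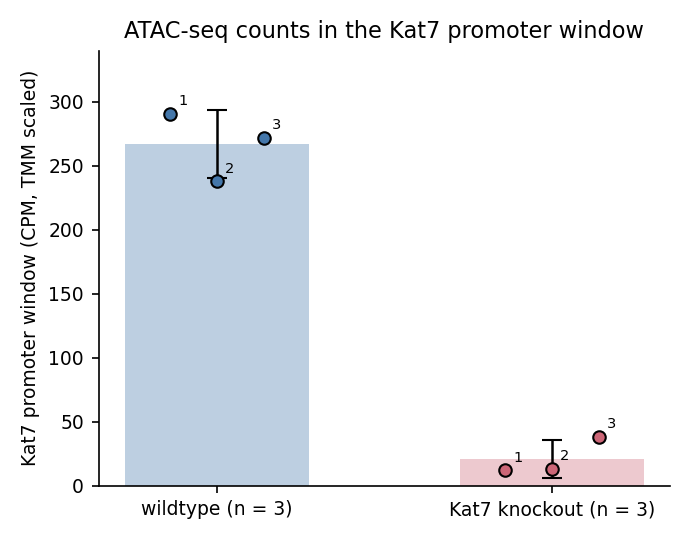
ATAC-seq signal in the Kat7 promoter window, in TMM-scaled CPM, for each of 3 wildtype and 3 knockout libraries (points, numbered by replicate), with bars at the mean and error bars of 1 SD. The wildtype libraries lie between 238.3 and 290.7 CPM and the knockout libraries between 11.9 and 38.3 CPM.

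Loss of accessibility was the more frequent change. Of 24817 windows tested, 5011 fell (20.2%), 1578 rose (6.36%) and 18228 did not pass. At least 2-fold changes numbered 1807 lower and 220 higher, and at least 4-fold changes 121 lower and 4 higher. Of the windows that fell, 4889 had every knockout library below every wildtype library, and of those that rose, 1387 had every knockout library above; over all tested windows 9469 (38.2%) were separated in this way in either direction, against 10% by chance. The higher share of all calls was 23.9%, and it was 35.6% with library totals only and 47.8% after loess normalisation. The number of higher windows depended on single libraries, with 689 without wildtype library 1 and 3177 without knockout library 1.

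Besides Kat7, whose counts may have fallen through the deletion itself, the largest losses were at promoters of genes of varied function. They included Hdx, an X-linked homeobox gene (15.8 ± 2.30 to 1.65 ± 1.29 CPM, log2 fold change -3.27, SE 0.194, adjusted p = 2.99e-49), and Uggt2, a glycoprotein quality-control enzyme of the endoplasmic reticulum (27.2 ± 3.05 to 3.07 ± 1.58 CPM, log2 fold change -3.15, SE 0.152, adjusted p = 1.91e-89). Pgr, the progesterone receptor, fell from 31.3 ± 1.78 to 4.19 ± 2.11 CPM (log2 fold change -2.90, adjusted p = 7.13e-86), and Adamts3, a procollagen peptidase, from 38.6 ± 3.62 to 5.73 ± 2.39 CPM (-2.76, adjusted p = 2.55e-86). Plppr1, a gene of neurite growth (-2.77), fell about as much. Without knockout library 3 the decline at Hdx was larger (-4.07). Fmn2, a formin of actin assembly (-2.34), and Jcad, a gene of cell junctions (-2.36), had higher wildtype levels, at 58.7 ± 9.74 and 46.7 ± 5.92 CPM. Usp29, whose window shares bases with another and is less certain, had -3.19, which did not pass with libraries 2 and 3 alone (adjusted p = 0.0574, the highest of the alternatives, which began at 1.55e-191).

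Among the gains, bitter taste receptor genes and Foxn1 stood out. Tas2r106 rose from 0.569 ± 0.185 to 2.24 ± 0.354 CPM (log2 fold change 1.98, SE 0.475, adjusted p = 0.000215) and Tas2r131 from 0.946 ± 0.332 to 3.54 ± 0.687 CPM (1.92, adjusted p = 1.62e-06); both encode taste receptors and had few counts. The neighbouring genes Aadac (6.88 ± 2.77 to 20.5 ± 2.09 CPM, 1.59, adjusted p = 4.96e-28) and Aadacl2 (3.89 ± 1.65 to 12.2 ± 0.902 CPM, 1.68), which encode arylacetamide deacetylases, rose together on chromosome 3. Cpvl, a serine carboxypeptidase gene (1.63), the zinc finger gene Zfp872 (1.36) and Pramel31 (1.36), a gene of the PRAME-like family, also rose.

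**Figure D2:**
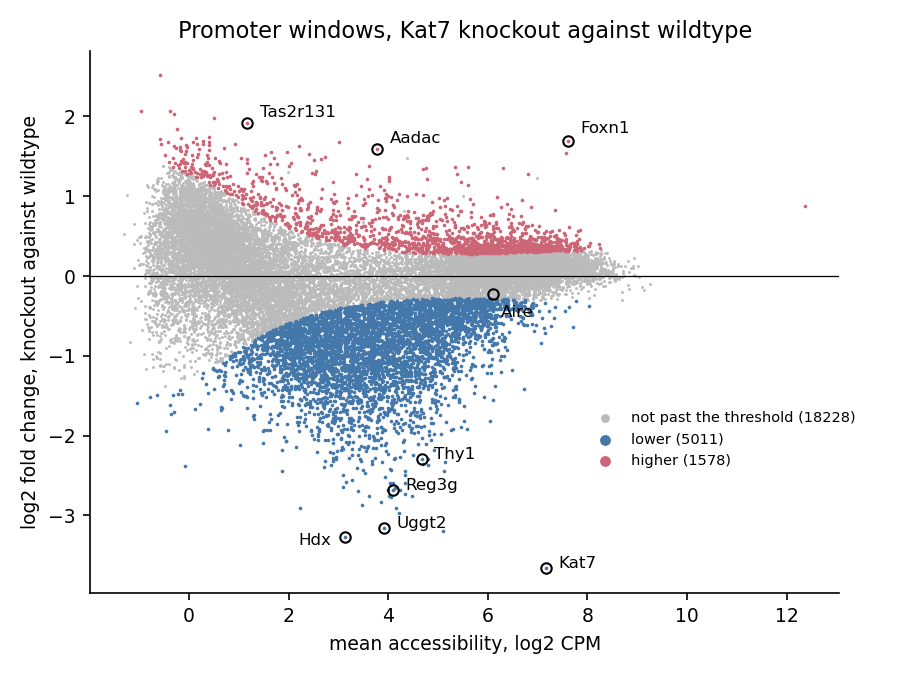
Log2 fold change of each tested promoter window, knockout against wildtype, over its mean accessibility in log2 CPM, with windows past an adjusted p of 0.05 in colour and named genes circled. The 5011 lower windows lie mostly at intermediate accessibility, and Kat7 lies at -3.66.

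Direction depended on how accessible a promoter was. Windows were ranked by mean log2 CPM over all libraries and split into quartiles with median levels of 1.21, 4.13, 27.7 and 107 CPM. In the second quartile 2015 windows fell (32.5%) and 284 rose, and in the third 2681 fell (43.2%) and 576 rose, whereas in the first 84 fell and 140 rose and in the fourth 231 fell and 578 rose. After loess normalisation, which removes a trend with accessibility, 1435 fell and 1049 rose in the second quartile and 1859 fell and 2129 rose in the third. The balance turned to losses in the first, where 451 fell and 160 rose, and was nearly even in the fourth, where 1456 fell and 1425 rose. The median log2 fold change of a knockout library against the wildtype mean was -0.28 ± 0.20 in the second and -0.19 ± 0.09 in the third quartile (SD, n = 3; exact permutation p = 0.1 in both, the smallest possible). It was 0.31 ± 0.48 in the first (exact p = 0.3) and 0.10 ± 0.17 in the fourth (exact p = 0.5). Knockout library 1 stood apart in both, with -0.24 in the first quartile, where the others had 0.53 and 0.64, and 0.29 in the fourth, where they had 0.02 and -0.01. It also differed in the second (-0.51 against -0.21 and -0.13) and in the third (-0.09 against -0.25 and -0.23).

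**Figure D3:**
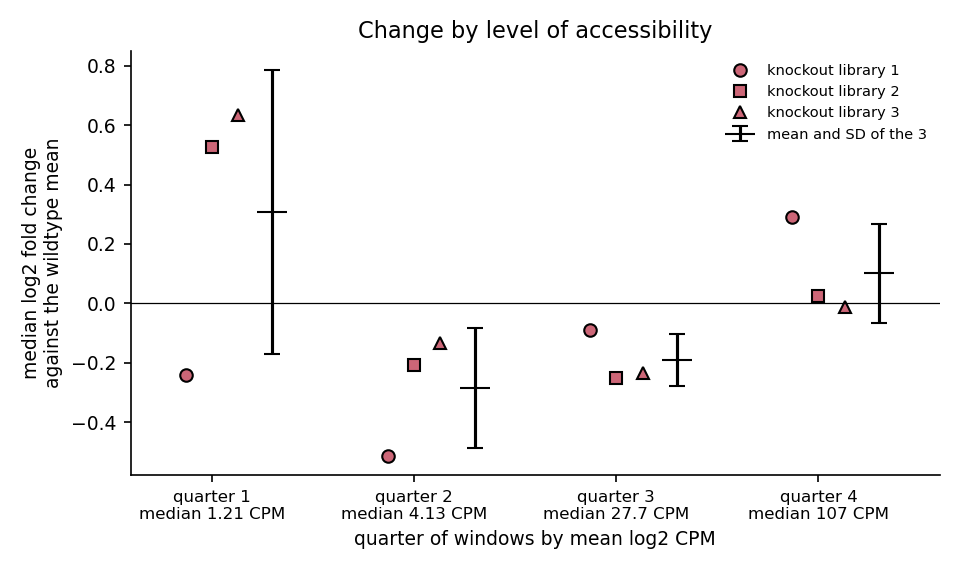
Median log2 fold change of each knockout library against the wildtype mean, by quartile of windows ranked by mean accessibility, with the mean and SD of the 3 libraries in black. All 3 libraries lie below 0 in the second and the third quartiles, and library 1 is apart from libraries 2 and 3 in each quartile.

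Foxn1, the transcription factor that sets thymic epithelial identity, had the largest gain among 9147 windows with a mean count of at least 500. Its window rose from 92.9 ± 24.5 to 299.6 ± 30.8 CPM (log2 fold change 1.69, SE 0.131, adjusted p = 4.98e-36), and that of the adjacent Slc13a2os from 97.0 ± 27.8 to 281.8 ± 33.4 CPM (1.54, adjusted p = 2.06e-30). Chosen after their values were seen, the next promoters on either side, Unc119 (44.4 ± 7.64 to 112.8 ± 10.5 CPM, 1.35) and Slc13a2 (65.5 ± 7.97 to 158.3 ± 14.6 CPM, 1.27), rose as well. These 4 windows span 84.7 kb of chromosome 11, from 78340522 to 78425185, with fold changes of 2.42 to 3.23. The next promoter on either side did not pass: Pigs, 10.1 kb away and in a window that overlaps that of Aldoc, had a log2 fold change of -0.02, and Slc46a1, 37.5 kb away, -0.25 (adjusted p = 0.0799). Beyond it, the overlapping windows of Aldoc (-0.85), Proca1 (-0.76) and Rab34 (-0.44) fell. With libraries 2 and 3 of each group alone, Foxn1 (1.51, adjusted p = 0.0763) and Slc13a2os (1.35, adjusted p = 0.109) did not pass; these were the highest adjusted p among their alternatives, which began at 1.57e-148 and 7.13e-128.

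**Figure D4:**
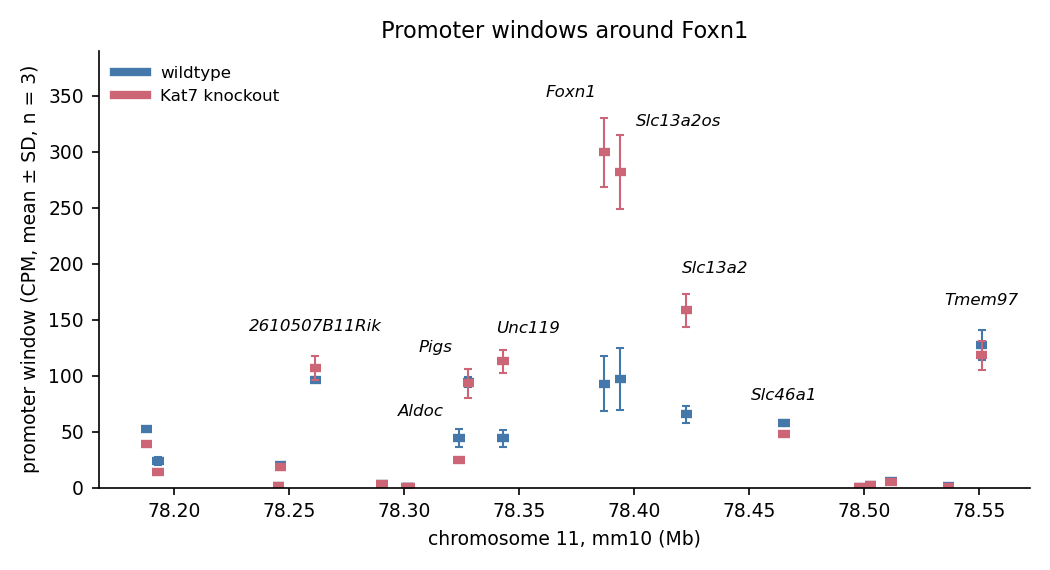
Promoter windows around Foxn1 on chromosome 11 (mm10), drawn to scale, with mean TMM-scaled CPM of 3 wildtype and 3 knockout libraries as horizontal bars and 1 SD as error bars. The 4 windows from Unc119 to Slc13a2 are higher in knockout by 2.42-fold to 3.23-fold, and Pigs and Slc46a1 on either side are not.

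The promoter of Aire, the factor that drives expression of tissue-restricted self-antigens in these cells, did not pass. It had 73.9 ± 3.03 CPM in wildtype and 63.3 ± 5.84 CPM in knockout (log2 fold change -0.22, SE 0.115, adjusted p = 0.149; chromosome 10, 78041580 to 78046580), and its window shares bases with 1 other. The value was below 0 in all 18 alternatives, from -0.33 to -0.16, and passed in 10 of them, with adjusted p from 6.24e-05 to 0.701.

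Of 25 genes of mTEC maturation and antigen presentation, 6 fell and none rose (6 and 0 adjusted over the list alone), with a median of -0.12. Random lists of like accessibility had a median of 0.08. That of this list lay at their 0.01th percentile. Ccr7, the receptor that draws cells to CCL21, fell from 49.9 ± 5.11 to 23.3 ± 0.843 CPM (log2 fold change -1.10, adjusted p = 2.88e-20). The genes of the chemokines Ccl17 (-0.95) and Ccl22 (-1.02) and of the transcription factor Irf4 (-0.76) fell too. Fezf2 (0.16, adjusted p = 0.394), Cd80 (0.05) and H2-Aa (-0.27, adjusted p = 0.107) did not pass. The list test did not pass (camera adjusted p = 0.214); it passed in 5 of 19 alternatives, whose adjusted p ranged from 0.0101 to 0.87. The lowest was that after loess normalisation, where 13 members were lower and 3 higher, and without knockout library 1, 12 members were lower (0.0274). Without wildtype library 2 or 3, 10 were lower. Of 12 genes of CCL21-producing mTECs, 2 rose and 2 fell (2 and 2 over the list alone), with a median of 0.13 and camera adjusted p = 0.214. Their basal keratin gene Krt5 (0.61) and Trp63 (0.50), a master regulator of stratified epithelium, rose, Krt15 fell (-1.13), and Ccl21a did not pass (0.08); without wildtype library 2, 4 were higher. Of 18 epithelial identity genes 3 rose and 2 fell (3 and 3 over the list alone), with a median of -0.01 whose sign changed with the scaling, a mean of 0.04 and a camera direction of higher (adjusted p = 0.49); Tbx1, a T-box factor of pharyngeal development, fell (-1.41, overlapping window) and Epcam did not pass (0.16). Without knockout library 1, 5 were higher and 6 lower, without wildtype library 2 or 3, 4 were lower, and with library totals 8 were higher and 6 lower.

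MTECs include subsets that resemble cells of other tissues, and promoters of several of their programmes fell. Of 13 enterocyte- and hepatocyte-like genes 9 fell and none rose (9 lower and 1 higher over the list alone), with a median of -0.88 (camera adjusted p = 0.000712; adjusted p = 0.319 with an estimated correlation, the highest of the alternatives, which began at 0.000101). The antimicrobial lectin gene Reg3g fell from 29.7 ± 2.81 to 4.63 ± 1.72 CPM (log2 fold change -2.69, adjusted p = 8.77e-77), and the transcription factor genes Hnf4g (-0.97) and Onecut1 (-0.88) fell. Of 11 ionocyte-like genes 8 fell and none rose (8 and 0 over the list alone), with a median of -0.81 (camera adjusted p = 0.0037; adjusted p = 0.453 with an estimated correlation and 0.1 after loess normalisation, from 0.00134 in other alternatives). They included Atp6v1b1, a proton pump subunit (-1.35), Bsnd, a chloride channel subunit (-1.10), and Pparg (-1.03). Of 15 ciliated-like genes 8 fell and none rose (9 lower and 1 higher over the list alone), with a median of -0.61 (camera adjusted p = 0.0169; adjusted p = 0.724 with an estimated correlation and 0.0691 with a mean count of at least 50, from 0.0042 in other alternatives). The axonemal genes Tekt1 (-1.51), Dnah5 (-1.30) and Cfap43 (-0.85) fell, and Foxj1, the factor that starts ciliogenesis, did not pass (-0.22, adjusted p = 0.183). Loess normalisation brought the medians of these lists closer to each other and to no change. The enterocyte- and hepatocyte-like list had -0.42 (9 lower, 2 higher), the ionocyte-like -0.45 (6 and 1) and the ciliated-like -0.27 (7 and 1).

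Tuft-like genes moved the other way. Of 19, 8 rose and 1 fell (8 and 1 over the list alone), with a median of 0.27 (camera adjusted p = 0.00206; adjusted p = 0.687 with an estimated correlation, the highest of the alternatives, which began at 7.99e-05). The taste transduction genes Gnat3 (1.18) and Plcb2 (0.73), the actin regulator Avil (1.00, overlapping window), the leukotriene enzyme gene Alox5 (0.83) and the lineage factor Pou2f3 (0.45) rose, Dclk1 fell (-0.51), and Trpm5 did not pass (0.27, adjusted p = 0.104). After loess normalisation 14 members were higher. The list also holds the bitter taste receptor genes Tas2r131 (1.92), which rose, and Tas2r108 (0.59, adjusted p = 0.154), which did not pass. This result and the gain of the taste receptors are therefore not independent.

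The other mimetic programmes did not pass the camera test with the preset correlation. Fry called the neuroendocrine-like (adjusted p = 0.0469), muscle-like (0.0469) and microfold-like (0.048) lists lower. These were the lowest adjusted p of their alternatives, which reached 0.942, 0.87 and 0.924. Fry tests each list by itself. Random lists matched on accessibility had medians of -0.245 for the neuroendocrine-like, -0.405 for the muscle-like and -0.0979 for the microfold-like list. The medians of the lists themselves lay at percentiles 36.91, 79.48 and 88.33. The keratinocyte-like median lay at percentile 67.91 (matched median -0.287). The fry calls thus do not show a fall beyond that of windows of like accessibility. Of 14 neuroendocrine-like genes 1 rose and 5 fell (1 and 5 over the list alone; median -0.31, camera adjusted p = 0.17), among them the receptor gene Ret (-1.02) and the prohormone convertase gene Pcsk1 (-0.83); after loess normalisation 5 were higher and 4 lower, with a median of -0.05. Of 16 muscle-like genes 1 rose and 7 fell (1 and 8 over the list alone; median -0.25, adjusted p = 0.116); after loess normalisation 4 were higher and 2 lower. Of 18 keratinocyte-like genes 1 rose and 7 fell (1 and 7 over the list alone; median -0.21, adjusted p = 0.363), but after loess normalisation 8 were higher and 2 lower. Without wildtype library 1, 4 were lower, and without wildtype library 3 or knockout library 2 3. Of 9 microfold-like genes 3 fell and none rose (3 and 0 over the list alone): Sox8 (-1.14, overlapping window), Gp2 (-1.01) and Ccl20 (-0.79), the last of which did not pass after loess normalisation (adjusted p = 0.113, the highest of alternatives from 2.9e-08). After loess normalisation 3 were higher and 3 lower. Their median was 0.08, with a sign that changed with the scaling, their mean -0.22 and their camera direction lower (adjusted p = 0.695).

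**Figure D5:**
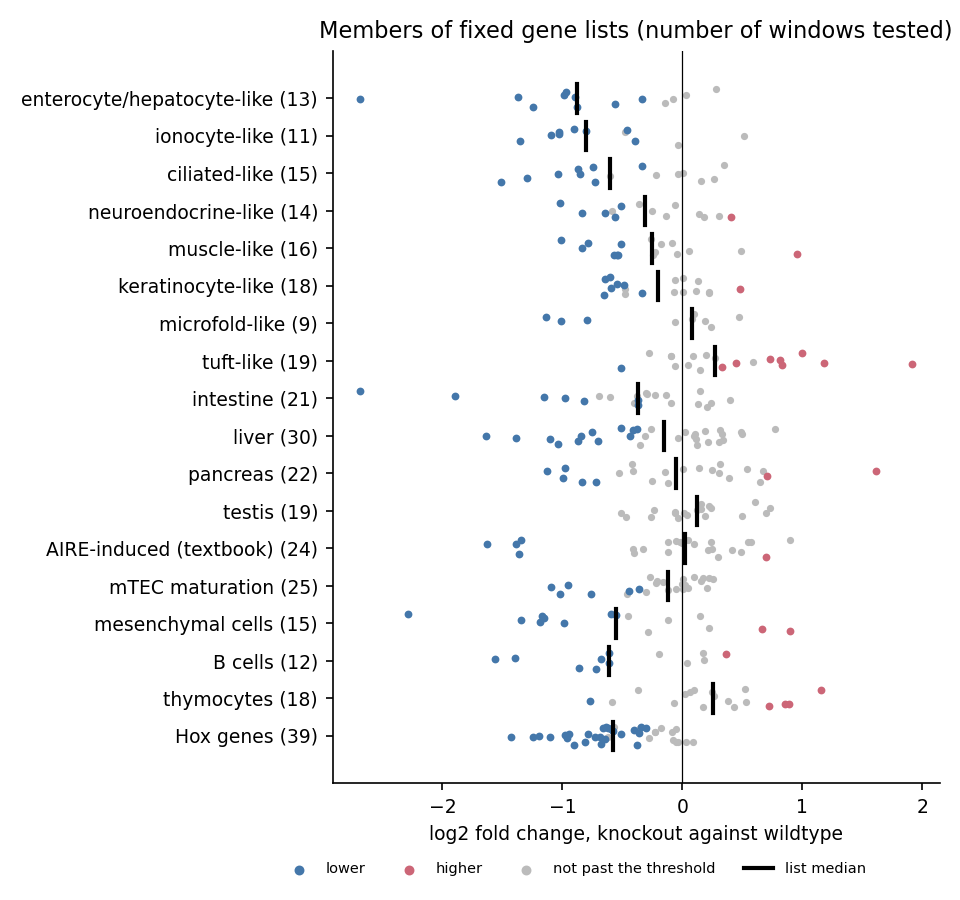
Log2 fold change, knockout against wildtype, of each tested window in 18 lists fixed before the data were examined, with windows past an adjusted p of 0.05 in colour and the median of each list as a bar. Members of the enterocyte- and hepatocyte-like, ionocyte-like and ciliated-like lists lie mostly to the left and those of the tuft-like list mostly to the right; the medians of the AIRE-induced, pancreas and microfold-like lists changed sign with the scaling.

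Promoters of tissue-restricted genes were mixed. Of 24 genes known from the literature as AIRE-induced, 4 fell and 1 rose (4 and 1 over the list alone); the median was 0.02, with a sign that changed with the scaling, the mean -0.10 and the camera direction lower (adjusted p = 0.589). Those that fell were Npy, a neuropeptide gene (16.8 to 5.41 CPM, log2 fold change -1.63, SE 0.15, adjusted p = 1.64e-25), the casein gene Csn2 (-1.36), Ambp, a plasma protein gene (-1.39), and S100a8 (-1.35). Wfdc18, a secreted protein gene, rose (23.7 to 38.2 CPM), and Ins2 did not pass (-0.12). Of 8 genes known as FEZF2-dependent 3 rose and 4 fell (3 and 4 over the list alone; median -0.16, adjusted p = 0.695), with Apoc3 (-1.26, overlapping window) and Ttr (-1.03) lower and Crp higher (0.58); after loess normalisation 3 were higher and 2 lower, and without wildtype library 3, knockout library 1 or knockout library 2, 1 was higher. Of 21 intestinal genes 7 fell and none rose (9 and 0 over the list alone; median -0.37, adjusted p = 0.0255; adjusted p = 0.87 with an estimated correlation), with Apoa4 (-1.89, overlapping window), Guca2b (-1.16) and Cdx2 (-0.98) as examples beside Reg3g. Matched random lists had a median of -0.18. The intestinal median lay at percentile 12.95, within the middle 95%. That call was also lost after loess normalisation (0.288), with TMM on the most accessible windows (0.0721), without wildtype library 3 (0.0708), without knockout library 1 (0.0649), with libraries 2 and 3 alone (0.0594) and with fry (0.0508), and the lowest adjusted p was 0.00576. Of 30 liver genes 12 fell and none rose (13 and 0 over the list alone; median -0.15, adjusted p = 0.16, past 0.05 in 2 alternatives, with a range of 0.0208 to 0.87), among them Kng1 (-1.10) and Ahsg (-0.85); 9 were lower after loess normalisation, and Alb did not pass (0.49).

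Of 22 pancreas genes 2 rose and 5 fell (2 and 5 over the list alone), with a median of -0.06 whose sign changed with the scaling (adjusted p = 0.742); the acinar factor Ptf1a (-1.13) and Ctrb1 (-0.98) fell. After loess normalisation 5 were higher and 4 lower, and without wildtype library 2, knockout library 2 or knockout library 3 none was higher. Of 27 secretory gland genes 2 rose and 2 fell (0 and 2 over the list alone; median 0.29, adjusted p = 0.102, past 0.05 in 3 alternatives with a lowest of 0.000819 and a highest of 0.87). Without knockout library 1 the counts were 7 higher and 2 lower with a median of 0.58, and without wildtype library 1, wildtype library 2, knockout library 2 or knockout library 3 none was higher. Of 26 neuronal and retinal genes 3 rose and 5 fell (4 and 5 over the list alone), with a median of -0.08 whose sign changed with the scaling (adjusted p = 0.589, with fry 0.048, in a range to 0.939); Camk2a (-0.87) and Gad2 (-1.03) fell. After loess normalisation 8 were higher and 6 lower, and with TMM on the most accessible windows 1 was higher and 8 lower. Leaving out any library but knockout library 3 gave 0 or 1 higher. Of 19 male germ cell genes 0 passed in edgeR, 0 in DESeq2 and 0 in limma-voom (0 over the list alone), with 0 higher and 1 lower at an unadjusted p of 0.05, a median of 0.12 and camera adjusted p = 0.437. Without knockout library 1, 4 were higher and 1 lower, and with sample weights in limma-voom 4 were higher and 2 lower.

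Most Hox genes, which pattern the body axis, fell. Windows of like accessibility fell as well (matched median -0.35, percentile of the Hox median 4.39). Of 39, 25 fell and none rose (28 and 0 over the list alone), with a median of -0.58 (camera adjusted p = 3.37e-08; adjusted p = 0.318 with an estimated correlation). Hoxb2 (-1.43, adjusted p = 1.81e-24), Hoxc13 (-1.25) and Hoxc9 (-1.19) were among them. After loess normalisation 14 were lower and 6 higher, with a median of -0.16, and the list did not pass (0.0761; range over the alternatives 2.53e-09 to 0.318). Clustered protocadherin genes, which give neurons their surface identity, went the other way: of 55, 15 rose and 6 fell (18 and 6 over the list alone), with a median of 0.47 (camera adjusted p = 2.56e-06; adjusted p = 0.687 with an estimated correlation and 0.0629 with a mean count of at least 50, from 7.85e-08). Pcdhb17 (1.46, overlapping window) and Pcdhb13 (1.06) rose, and 29 were higher and 1 lower after loess normalisation. Higher windows numbered 8 with TMM on the most accessible windows, 10 without wildtype library 1 and 25 without knockout library 1.

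Receptor genes of smell, which are closed in most tissues, had positive medians, while most of their windows did not pass in either direction. Of 1055 olfactory receptor windows 27 rose and 21 fell (7 and 12 over the list alone), with a median of 0.54 (camera adjusted p = 1.33e-09; adjusted p = 0.87 with an estimated correlation), and of 307 vomeronasal receptor windows 18 rose and 1 fell (1 and 0 over the list alone), with a median of 0.68 (camera adjusted p = 5.7e-11; adjusted p = 0.87 with an estimated correlation). Among the former, Olfr1033 (-1.17) and Olfr157 (-1.40) fell. The olfactory call was lost after loess normalisation (0.237) and with a mean count of at least 50, where the median was -0.07 (0.873; the lowest was 1.81e-21). Fry called neither (0.557 and 0.426), and the lowest vomeronasal value was 4.05e-23. Without knockout library 1 the counts were 348 higher and 20 lower olfactory and 159 higher and 1 lower vomeronasal windows. Higher windows numbered 8 and 3 without knockout library 2, 8 and 3 without knockout library 3, and 10 and 7 without wildtype library 1. Without wildtype library 3, 12 olfactory windows were lower and 10 vomeronasal windows higher, as many as without wildtype library 2.

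Markers of other cells that a sort of thymic cells can carry along were also measured, and they moved in different directions. Of 15 mesenchymal genes 8 fell and 2 rose (8 and 2 over the list alone; median -0.55, camera adjusted p = 0.0126; adjusted p = 0.724 with an estimated correlation, 0.298 after loess normalisation and 0.0521 with a mean count of at least 50, from 0.00233). Matched lists had a median of -0.33. The mesenchymal median lay at percentile 16.31, within the middle 95%. With loess normalisation that median was -0.115, with 6 lower and 3 higher, and the B cell median was -0.147, with 3 lower and 1 higher. Thy1 fell from 42.3 ± 2.95 to 8.66 ± 0.930 CPM (log2 fold change -2.29, adjusted p = 5.1e-71), and Pdgfrb (-1.17) and Postn (-1.19) fell. Of 12 B cell genes 7 fell and 1 rose (7 and 1 over the list alone; median -0.61, adjusted p = 0.019; adjusted p = 0.453 with an estimated correlation, 0.253 after loess normalisation and 0.0826 with libraries 2 and 3 alone, from 0.00159), with Ebf1 (-1.56) and Cr2 (-1.39) as examples. Of 18 thymocyte genes 4 rose and 1 fell (4 and 2 over the list alone; median 0.25, adjusted p = 0.0388; adjusted p = 0.687 with an estimated correlation), with Themis higher (1.16) and Lat lower (-0.77, not past after loess normalisation, 0.106, the highest of alternatives from 4.22e-09). The thymocyte call was lost in 12 of its alternatives, whose adjusted p ranged from 0.00924 to 0.687, while the median stayed above 0 (0.16 to 0.52). After loess normalisation 11 were higher and 0 lower, and without wildtype library 1, wildtype library 3 or knockout library 3, 2 were higher. The summed thymocyte windows held 206.7 ± 6.52 CPM in wildtype and 221.3 ± 16.3 CPM in knockout without TMM scaling (exact permutation p = 0.3, n = 3 per group).

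Of 18 myeloid and dendritic cell genes 7 fell and 1 rose (7 and 1 over the list alone), with a median of -0.03 whose sign changed with the scaling (adjusted p = 0.412, with fry 0.01, in a range to 0.987); Cx3cr1 (-1.20) and Sirpa (-0.93) fell. After loess normalisation 5 were higher and 3 lower, with a median of 0.11. Of 13 endothelial genes 5 fell and 2 rose (5 and 2 over the list alone; median -0.23, adjusted p = 0.348), with Pecam1 (-1.33) and Kdr (-1.37) lower and Tek higher (0.72). Of 10 erythroid genes 5 fell and none rose (5 and 0 over the list alone; median -0.38, adjusted p = 0.0554, past 0.05 in 6 alternatives, with a range of 0.00872 to 0.687). Of 10 cortical thymic epithelial genes 3 rose and 2 fell (3 and 2 over the list alone; median 0.14, adjusted p = 0.344), with the peptidase gene Enpep (0.71) and the thymoproteasome gene Psmb11 (0.53) higher and Prss16 not past (0.20, adjusted p = 0.219). The cortical, thymocyte, B cell and myeloid lists share 0 genes with other lists.

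By list tests 7 of 46 lists were lower and 5 higher with the preset correlation. With an estimated correlation 0 passed in camera (smallest adjusted p 0.318; 4 at an unadjusted p below 0.05), and fry called 12 lower and 2 higher. Against random lists matched on accessibility, which ignore correlation between genes, the medians of 6 of these 12 lists lay outside the middle 95%: enterocyte- and hepatocyte-like (percentile 0.18), ciliated-like (0.12), tuft-like (100), thymocyte (99.95), vomeronasal (100) and protocadherin (100). Those of the ionocyte-like (3.78), B cell (4.5), Hox, intestinal and mesenchymal lists lay within. No matched lists were drawn for olfactory receptors. By chromosome, the share of lower windows differed from that elsewhere on chromosomes 1 (23.0%), 15 (24.4%), 7 (18.1%), 16 (16.2%) and X (16.3%), with Fisher's exact test and adjusted p between 0.018 and 0.0433, and the share of higher windows on chromosomes 2 (4.47%), 9 (8.36%) and 18 (9.56%; adjusted p 0.00407 to 0.0206). Without knockout library 2 no chromosome differed in its share of lower windows. Fisher's test takes windows as independent, while lower windows lay near other lower windows, so its p for them are too small. The 100 highest windows held 4.06 ± 0.05% of counts in wildtype and 4.40 ± 0.08% in knockout, and mitochondrial windows 0.387 ± 0.13% and 0.701 ± 0.0734% (SD, n = 3, exact permutation p = 0.1 for each, the smallest possible). The mitochondrial ND6 window alone held 46891, 71830 and 71742 counts in wildtype and 120927, 121464 and 105970 in knockout libraries 1 to 3. The mitochondrial rise of 0.314 points thus makes up most of the rise of 0.34 points in the 100 highest windows.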

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

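Windows that share no base with another, and libraries 2 and 3 of each group alone, were alternatives chosen after seeing the data; the others were fixed beforehand. The number of lower windows, 5011, stayed within 1.5 times that value under every alternative run, from 3818 against a 1.2-fold change to 6806 with sample weights in limma-voom. The number of higher windows, 1578, did not: it was 2937 with library totals, 4723 with sample weights, 3937 with a mean count of at least 50, 4763 after loess normalisation, 534 against a 1.2-fold change and 2664 with libraries 2 and 3 alone. With the replicate block it was 2824, and 5537 windows were lower. Leaving out 1 library gave 689 (without wildtype library 1) to 3177 (without knockout library 1) higher windows and 4227 (without knockout library 2) to 5709 lower ones. The cause was not tested for any of these. DESeq2 called 1918 higher and 4158 lower windows among 21930, limma-voom 1594 and 4974.

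By camera 7 lists were lower and 5 higher. With an estimated correlation 0 were lower and 0 higher, with fry 12 and 2, and after loess normalisation 3 were lower; leaving out 1 library gave 6 to 9 lower and 5 to 8 higher lists, with 8 higher without wildtype library 3 and without knockout library 3. Of the 12 list calls, 6 were lost after loess normalisation, and the thymocyte call was lost under 12 of 19 alternatives. The median of olfactory receptors reversed to -0.0657 with a mean count of at least 50, where the weakest windows are gone. After loess normalisation Dmkn (0.0376) and Ifi44 (0.0408) reversed, and of the 5011 lower windows 3511 stayed lower while 237 of all calls changed sign. The cause was not tested.

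The share of lower windows differed on 5 chromosomes and that of higher windows on 3; with libraries 2 and 3 alone these were 8 and 8. Leaving out 1 library gave 0 (without knockout library 2) to 9 (without knockout library 1) and 3 (without wildtype library 3) to 10 (without knockout library 1), with 8 and 5 without wildtype library 2 and 3 and 5 without knockout library 3. The medians by quartile moved by less than their SD with library totals, DESeq2 size factors, a prior count of 0.5 and each library left out; they were not run with TMM on the most accessible windows or with loess normalisation, which sets such medians by construction. Without knockout library 1 the first quartile had 0.61 and the fourth -0.0019. The difference in the share of counts in the highest windows was 0.34 points for 100 windows, most of it mitochondrial, and 1.46 for 1000. Deviations from the group mean correlated across windows at 0.374, 0.0284 and 0.389 for libraries of the same number. Knockout libraries 1 and 3 were closest to the wildtype library of their own number, and knockout library 2 to wildtype library 3 (0.308). Whether replicate numbers pair the libraries was therefore left open. At this depth and number of libraries 36.8% of simulated 1.5-fold changes were recovered where few windows changed. Depth was not tested apart from accessibility: in the first quartile 140 windows rose and 84 fell (160 and 451 after loess normalisation), but calls among weak windows also moved with knockout library 1 (27 higher olfactory windows with it, 348 without it).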

Other observations

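The tests on cortical cells, overlapping windows, olfactory and vomeronasal receptors, the lower windows of the second and the third quartiles, and Tas2r genes were chosen only after the result was seen. Many bitter taste receptor genes, chosen after their values were seen, rose: of 34 windows, nearly all of them on chromosome 6, 22 rose, 12 did not pass and none fell, with a median log2 fold change of 1.23. Tas2r118 (1.53), Tas2r117 (1.55) and Tas2r126 (1.02) rose besides those named before. A hypothesis was that they rise beyond windows of like abundance. The median lay at the 100th percentile of 10000 lists matched on mean accessibility (matched median 0.07), and again without knockout library 1 (27 higher, median 1.28 against 0.29), but this decides nothing, since the family was picked because its members were among the largest gains.

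Genes of KAT7 complexes and related enzymes were mixed beside Kat7. Of 10 complex genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), with a median of 0.16, a mean of -0.25, lowered by Kat7 itself, and a camera direction of higher (adjusted p = 0.427); Jade2 (0.45) and Brd1 (0.39), scaffold subunits, rose but did not pass against a 1.2-fold change (0.101 and 0.198, the highest of their alternatives, which began at 9.78e-09 and 3.31e-06). Of 9 other acetyltransferase genes 1 rose and 1 fell (1 and 1 over the list alone), with a median of 0.05 whose sign changed with the scaling (adjusted p = 0.407); Ep300 did not pass (0.30, adjusted p = 0.0637), and without wildtype library 2, 4 rose. Of 20 genes of AIRE partners 2 rose and 1 fell (1 and 1 over the list alone; median 0.15, adjusted p = 0.107), but 10 rose with library totals, none without wildtype library 1 and 12 of 19 with a mean count of at least 50, and the list was higher in 4 alternatives (adjusted p from 0.011 to 0.987). Of 16 NF-kB response genes 1 rose and 1 fell (1 and 1 over the list alone), of 19 interferon response genes 2 rose and 2 fell (2 and 2), of 16 p53 response genes 0 rose and 1, Eda2r (-0.57), fell (0 and 1), and of 19 housekeeping genes 2 rose and 1 fell (2 and 1). Their medians of 0.04, 0.05, 0.08 and 0.08 changed sign with the scaling, and camera adjusted p lay between 0.355 and 0.412. After loess normalisation 3 were higher and 8 lower, 6 and 5, 0 and 5, and 3 and 7, and without knockout library 1, 5 interferon response genes were lower. Of 20 cell cycle genes 0 passed in edgeR, DESeq2 or limma-voom (0 over the list alone), with 0 higher and 1 lower at an unadjusted p of 0.05 and a median of 0.02 whose sign changed with the scaling (adjusted p = 0.695); after loess normalisation 2 were higher and 4 lower, without knockout library 1, 4 lower and without wildtype library 2, 2 lower.

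Among gene families, 6 of 56 histone genes rose and 2 fell (5 and 2 over the list alone), with a median of 0.10 whose sign changed with the scaling (adjusted p = 0.0614, past 0.05 in 4 alternatives, with a range of 0.00149 to 0.87); 18 rose after loess normalisation, 10 without wildtype library 2, and 3 without wildtype library 1 or knockout library 1. H1f7, a testis linker histone, rose (1.00). Of 77 ribosomal protein genes 7 rose and 6 fell (5 and 5; median 0.16, adjusted p = 0.0681), but 25 rose with library totals, 29 after loess normalisation and 31 of 60 with a mean count of at least 50, 11 rose without wildtype library 2, 2 to 4 without wildtype library 1 or 3 or knockout library 1 or 2, and the list was higher in 8 of 19 alternatives (adjusted p from 0.00522 to 0.87). Of 347 zinc finger genes 32 rose and 47 fell (31 and 47), among them Zfp976 (-2.65) and Zfp970 (-1.86); the median was 0.06, with a sign that changed with the scaling, and the mean -0.0027 (adjusted p = 0.294, from 0.0367 to 0.87 in the alternatives). The balance reversed to 117 higher and 60 lower after loess normalisation and 95 higher and 52 lower with a mean count of at least 50, and was 12 higher and 40 lower without wildtype library 1 and 20 and 39 without knockout library 2. Of 66 defensin genes 3 rose and 9 fell (3 and 8), with Defb6 (-0.90) and Defb1 (-0.77) lower although the median was 0.36 (adjusted p = 0.0916, past 0.05 in 5 alternatives, with a range of 3.37e-05 to 0.87). Over the alternatives the defensin median ranged from -0.65 to 0.59, and 23 rose without knockout library 1. Of 64 Spink and Serpin genes 5 rose and 13 fell (5 and 13), with a median of -0.11 whose sign changed with the scaling (adjusted p = 0.511); Serpina9 (-1.46) and Serpinb8 (-1.21) fell, and after loess normalisation 14 were higher and 9 lower. Without wildtype library 1, 2 were higher, without wildtype library 3, 3 higher and 8 lower, and without knockout library 1, 9 higher. Of 13 Klk1b kallikrein genes 5 fell and none rose (5 and 0; median -0.33, adjusted p = 0.0608, past 0.05 in 4 alternatives, with a range of 0.00601 to 0.87). Of 50 keratin-associated protein genes 2 rose and 6 fell (2 and 5), with a median of 0.12 whose sign changed with the scaling (adjusted p = 0.589); Krtap13-1 fell (-1.72). Without wildtype library 3, 3 were lower, and without knockout library 1, 6 were higher. Of 22 major urinary protein genes 0 passed in edgeR, DESeq2 or limma-voom (0 over the list alone), with 3 higher and 0 lower at an unadjusted p of 0.05 and a median of 0.45 (adjusted p = 0.0628, past 0.05 in 6 alternatives, with a range of 4.48e-05 to 0.87); 8 rose without knockout library 1.

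The gain at Unc119, Foxn1, Slc13a2os and Slc13a2 is a pattern with a technical reading. Reads shared between overlapping windows are excluded, since 0 of the 4 windows shares a base with another. The cortical list had a median of 0.137 (Tbata 88.8 to 106.0 CPM, Ctsl 86.0 to 85.0 CPM) where these windows rose by over 1. Enpep (0.71), Psmb11 (0.53) and Dll4 (0.46, overlapping window) of that list rose, and Cd83 (-0.57) fell. More cells of a cortical type are not excluded, since the test assumes that cortical promoters would rise as much as these windows. Extra copies of a DNA segment that holds the 4 windows stay open. Only 7 of 9147 windows with a mean count of at least 500 elsewhere rose by over 1 on the log2 scale. The 4 windows are neighbours, and the next promoters did not pass (that of Pigs in an overlapping window). The block was drawn after the values were seen and ends where the rise ends. Its edges therefore cannot favour copies over a rise of regulation. Such copies could come from a transgene built on the Foxn1 locus, a common driver of Cre recombinase in thymic epithelium. The labels name no driver. Whether the folds of the 4 windows are equal stays undecided (chi-square 6.6, 3 degrees of freedom, p = 0.0859). That test takes the 4 windows as independent, while they share the same 6 libraries and thus part of their error. A rise of Foxn1 regulation in knockout cells remains open as well and was not tested.

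The direction by accessibility is a pattern with 2 parts. For the olfactory and vomeronasal windows, a larger background share of reads in some libraries may account for the gain: only 2 knockout libraries, 2 and 3, lay above every wildtype library in median level (1.43 and 1.59 CPM against 0.615 to 1.0), and knockout library 1 had 0.745. Against the wildtype library of the same number, each knockout library was higher (0.745 against 0.615, 1.43 against 0.895 and 1.59 against 1.0 CPM). A pairing by number, which stayed open, would thus alter this comparison. A larger background would lower the share of counts in the strongest windows. The 1000 highest windows held 25.17%, 24.48% and 24.04% in knockout libraries 1 to 3 and 23.38%, 23.01% and 22.91% in wildtype libraries 1 to 3. Every knockout library thus lay above every wildtype library, while within each group the share fell as the receptor level rose. These shares go both ways and decide nothing. An opening of closed chromatin after loss of KAT7 cannot be told apart from a larger background, since the same libraries decide both. For the losses in the second and the third quartiles, a larger background in knockout libraries is excluded as the whole cause. The fourth quartile lay above the third in 3 of 3 knockout libraries. A trend with abundance shared by all windows was also considered. After loess normalisation 68.1% of the 4696 lower windows of these quartiles stayed lower, so these single losses went beyond the fitted trend. They had been picked as lower in the same libraries, and loess normalisation gave more calls over all windows (5201 lower and 4763 higher against 5011 and 1578). The share kept therefore does not measure how much of the losses such a trend accounts for. The excess of losses over gains cannot be told apart from such a trend, since lower windows were 84.5% of the calls in these quartiles before and 50.9% after loess normalisation, which sets the balance by construction; a loss in knockout cells also stays open.

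Knockout library 3 kept more Kat7 reads, 14.4% of the wildtype mean against 4.46% and 4.94%. More immune cells, which keep Kat7 and which the sort for mTECs would largely remove, cannot be told apart from other explanations. A gain below 0.05 had been set to count against them, and 48 thymocyte, B cell and myeloid windows together differed by -0.0179 of their level between library 3 and library 2 (843.9 and 859.5 CPM), but Blnk, Zbtb46 and Bcl11b alone held 41.5% of the sum in wildtype, a level that would hide a small share of such cells. More cells with an undeleted Kat7 allele may account for it: over 14271 windows library 3 was shifted from library 2 towards wildtype by 0.0962 of the difference between wildtype and knockout library 1 (95% bootstrap interval over windows 0.0933 to 0.0993), close to the difference of 0.0942 in Kat7 itself. Windows are not independent, so the interval is too narrow, and a library with a weaker effect for another reason remains open.

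Lower windows lay near other lower windows. Of 17196 pairs of next neighbours that share no base and start within 100 kb, 31.4% of those beginning with a lower window ended in another, against a mean of 23.2% and a highest value of 25.1% in 1000 shuffles within levels of accessibility, which fits the hypothesis that neighbouring promoters lose accessibility together; shared copies or enhancers were not tested. A second hypothesis, that promoters of long genes lose accessibility more often, was left undecided: in the third quartile, among 2302 lower and 2799 other windows that share no base with another, genes of lower windows were longer by 1.67 kb at the median (22 against 20.4 kb, permutation p = 0.102). Over all windows with a length they were longer in the second quartile (16.1 against 10.6 kb) and the third (19.7 against 18.5 kb) and shorter in the fourth (20.4 against 25.4 kb). A p of 0.05 or more had been set to count against the hypothesis, but a missed threshold excludes nothing, and the quartiles went both ways.

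The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 5011 lower and 1578 higher windows and the highest other split 0 and 0, so that 1 of 10 splits gave as many in each direction. For lists, the real split gave 7 lower and 5 higher, and the highest other split 12 counting whichever direction had more lists. Of 10 splits, 9 reached the real number of lower lists and 9 that of higher lists. Every other split mixes the genotypes in unequal parts, so part of the genotype difference remains in each. Taking the larger direction also favours the other splits. This comparison therefore cannot decide whether list counts of this size arise without a difference between groups. At an unadjusted p below 0.05 the real split had 8746 windows and the other 9 had 14 to 2597.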
